A study of Mus musculus with 12 samples.

How the data were processed

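RNA of the mouse lateral septum, a forebrain nucleus below the corpus callosum, was measured by bulk RNA sequencing in 12 libraries. Per the labels, 6 libraries came from mice injected with saline and 6 from mice injected with CFA, in pain research the usual short form of complete Freund's adjuvant, an emulsion that causes lasting local inflammation. All were labelled day 3 and wild type. Per the labels' protocols, RNA was harvested with Trizol, 0.2 µg per sample entered library preparation, and paired reads of 150 bases were made on an Illumina NovaSeq. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to the mouse build mm10. The read counter, its strand setting and the annotation release are not given in the sources used here.

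The authors deposited FPKM (fragments per kilobase of gene length, scaled to the reads counted in each library), 1 column per library, with a gene length per gene. Gene length in bases, in the same deposited table, is the length the authors divided by. FPKM multiplied by gene length took values in whole steps within each library, so reads per gene were recovered from the steps. Of the recovered values, 100% lay within 0.01 read of a whole number. The recovered reads summed to between 33.6 and 39.2 M reads per library. The divisor implied by the steps was 0.990 to 1.03 times that sum, for a reason not given in the sources used here. Gene IDs and symbols were taken from the table. Of its IDs, 54495 were in GENCODE M21, and 98.3% of those had the coordinates and strand of that annotation, so coordinates are those of GRCm38 (mm10), counted from 1. A further 6 columns of per-sample values, in a separate table, matched no sample of the series and were not used.

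Groups were taken from the labels. Genes with FPKM of at least 1 in at least 6 libraries were tested. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with eBayes and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over the 13345 genes tested and a threshold of 0.05. Fold changes are CFA minus saline on the log2(FPKM + 1) scale, which understates the change of genes with low values. FPKM is not a count, so no count model gave a main result. Gene lists of pathways, cell types and quality measures, 49 in all, were fixed before the data were examined, as were the tests, the other settings to be tried and the rule for named genes. Lists with at least 4 tested members were compared with other genes by limma's camera with a preset inter-gene correlation of 0.01, then with an estimated correlation. Fry was run beside it, which tests a list against no change and compares it with no other genes. The mean of each cell type and quality list per library was compared by an exact permutation test over all 924 assignments of 6 of the 12 libraries, two-sided.

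The rule for named genes took Tia1 and Tial1, the 4 members of the NF-kB list with the smallest p, up to 12 genes per direction past the threshold, filled with the smallest unadjusted p to 8 per direction where fewer than 5 passed, and up to 4 members of each fixed list with the smallest p. In the second of these, symbols that start with Gm and a digit, end in Rik or in -ps and digits, or are bare Ensembl IDs were passed over, a mean of at least 1 FPKM in a group was required, and ties went to the larger change. Genes outside the rule are named as chosen after their values were seen.

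The fit was tested on simulated reads with the means, spread and depths of these libraries, over 13345 genes. Of 50 genes changed by a log2 fold of 0.3, 13 (26%) were called in the right direction, of 50 changed by 1 it was 42 (84%), and of 50 changed by 1.5 it was 49 (98%). Of 13119 unchanged genes, 5 were called. Many genes were changed at once, which made the adjusted threshold easier to reach than in the real comparison, where 4 genes passed. These shares can therefore overstate what the real comparison could find. Both lists that were moved and 0 of 42 others were called with the preset correlation, but simulated genes were independent of each other, which real genes are not. Alternatives covered the pseudocount, the filter, the scaling, the variance model, voom on the recovered reads, a rank-sum test, thresholds, a block for the replicate number, left-out libraries and covariates. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.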

Results

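RNA of the lateral septum was profiled at day 3 in 6 libraries of the saline group and 6 of the CFA group, with recovered depths of 35.9 ± 1.63 M reads per library (SD, n = 6) for saline and 37.3 ± 1.44 M reads (SD, n = 6) for CFA. The series title names microglial TIA1 and NF-kB signalling in inflammatory pain, and its design compares the saline with the CFA group. No label says that the libraries came from separate animals, so p-values measure the spread between these samples, which may in part be technical. Each group held libraries with and without the Y-linked Ddx3y (below), so neither group came from 1 animal alone. The closest pair of libraries, saline 4 and saline 6, differed by a chi-square of 7.22 per degree of freedom, so no pair was treated as a repeat deposit of 1 library. That test covers counting error only and does not tell separate animals from repeat preparations of 1 animal.

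The first comparison asked which genes differed between CFA and saline. Mpeg1, which encodes the macrophage pore-forming protein perforin-2, rose from 4.76 ± 0.370 to 6.49 ± 0.237 FPKM (SD, n = 6 each). Ctss, the lysosomal protease cathepsin S of microglia and macrophages, rose from 23.4 ± 2.04 to 32.9 ± 2.75 FPKM. Wdfy1, an endosomal protein that helps relay signals of Toll-like receptors 3 and 4, fell from 8.43 ± 1.74 to 2.66 ± 0.244 FPKM; Gt(ROSA)26Sor, chosen after its values were seen, was also below every saline library in 5 of 6 CFA libraries. Nrip2, which encodes a nuclear receptor interacting protein, fell from 7.42 ± 0.610 to 5.32 ± 0.495 FPKM. For Mpeg1, Ctss, Wdfy1 and Nrip2, 6 of 6 CFA libraries lay outside the saline range. The groups did not overlap for 66 of the 13345 genes tested, where 29 would be expected by chance. For genes picked by their small p, such separation is no further support.

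These were the 4 genes, 2 higher and 2 lower, that passed the threshold among 13345 tested by limma with Benjamini-Hochberg adjustment. Wdfy1 (chromosome 1, 79702262 to 79776143, minus strand) had a log2 fold change of -1.35 (SE 0.10, adjusted p = 5.13e-05). Mpeg1 (chromosome 19, 12460779 to 12465284, plus strand) had 0.38 (SE 0.05, adjusted p = 0.0168). Ctss (chromosome 3, 95526786 to 95556403, plus strand) had 0.48 (SE 0.07, adjusted p = 0.0304). Nrip2 (chromosome 6, 128399296 to 128416427, plus strand) had -0.42 (SE 0.06, adjusted p = 0.0436). At an unadjusted p under 0.05 there were 1024 genes, 415 higher and 609 lower, where 667 would be expected by chance. The split was 2 higher and 1 lower after median ratio scaling, and 3 higher and 1 lower as TPM. Leaving out 1 library gave between 1 and 11 genes: 2 without saline 2, 11 without saline 3, 2 without saline 4, 1 without saline 5, 10 without CFA 1 and 1 without CFA 6. With Xist as a covariate, an alternative chosen after seeing the data because the groups differ in Xist, Wdfy1 passed (adjusted p = 0.00147) while Mpeg1 (0.37, adjusted p = 0.233), Ctss (0.45, adjusted p = 0.259) and Nrip2 (-0.44, adjusted p = 0.233) did not; without saline 3 and saline 5, also chosen after seeing the data, 6 genes passed, of which 1, Wdfy1, was among these 4. With the pan-neuronal list mean as a covariate, likewise chosen after seeing the data, 1 gene passed, Wdfy1.

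**Figure D1:**
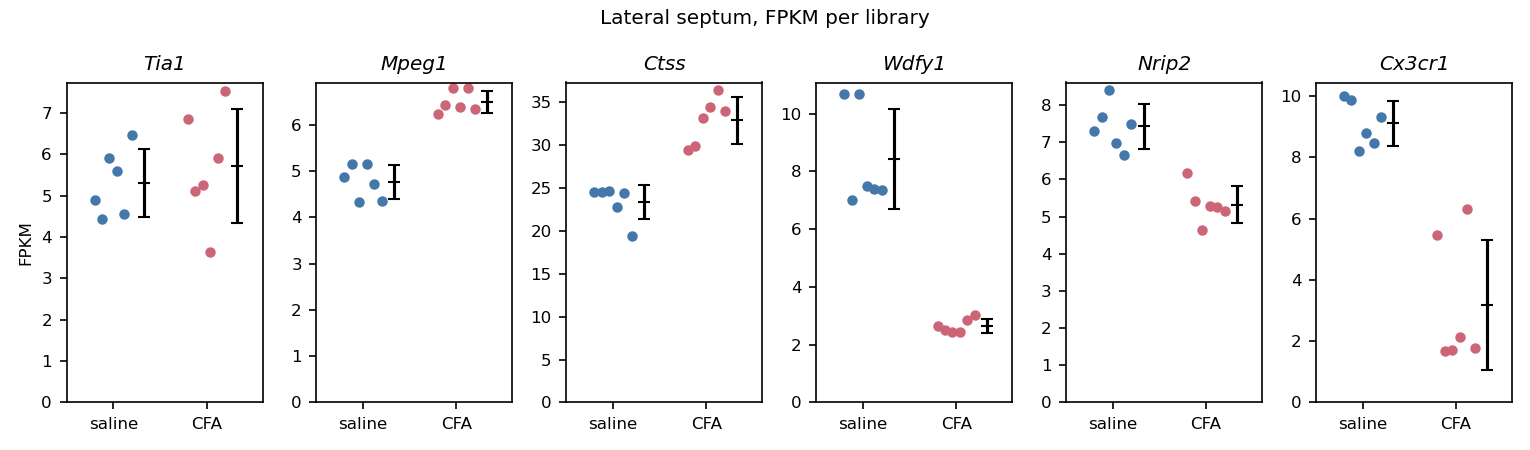
FPKM of 6 genes in each saline (blue) and CFA (red) library, 1 point per library, with the mean and SD (n = 6) in black; each vertical axis starts at 0. Wdfy1 lay at 2.66 FPKM on average in CFA against 8.43 in saline with no overlap, while the Tia1 values of the groups overlapped.

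Further genes with the smallest p did not pass the threshold by limma. Lyz2, a lysozyme of myeloid cells with the near-identical copy Lyz1, was 4.05 FPKM in saline and 7.77 in CFA (log2 fold change 0.78, adjusted p = 0.101). The complement genes C1qa (0.32, adjusted p = 0.140), C1qc (0.36, adjusted p = 0.143) and C4b (0.71, adjusted p = 0.143) and the cell cycle inhibitor Cdkn1a (0.50, adjusted p = 0.140) had positive values. So did B3galt5, a galactosyltransferase (0.30, adjusted p = 0.115). C4b can share reads with its copy C4a. Cx3cr1, the fractalkine receptor of microglia, was 9.10 ± 0.737 FPKM in saline and 3.18 ± 2.13 in CFA (SD, n = 6 each; log2 fold change -1.41, adjusted p = 0.115). Negative values were also found for Fgfrl1 (-0.36, adjusted p = 0.115), the histone gene H2afj (-0.40, adjusted p = 0.140), the membrane progestin receptor Paqr7 (-0.23, adjusted p = 0.156), Gpr165 (-0.35, adjusted p = 0.165) and the small nucleolar RNA Snora30 (-0.98, adjusted p = 0.165). Strand use in counting is not given, so overlapping and antisense genes cannot be told apart in any of these values.

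Tia1, the RNA-binding protein of the series title, was 5.31 ± 0.815 FPKM in saline and 5.72 ± 1.38 in CFA (SD, n = 6 each). Tia1 (chromosome 6, 86404219 to 86433405, plus strand) had a log2 fold change of 0.07 with a 95% interval of -0.21 to 0.36, a ratio of 0.865 to 1.28 on the FPKM + 1 scale. The difference was within the spread between libraries (limma adjusted p = 0.939; exact permutation p = 0.621, 924 assignments, two-sided). Its relative Tial1 had 0.07 (adjusted p = 0.872). The transcript level does not measure TIA1 protein, and whole tissue does not separate microglia. Of 24 tested genes of TIA1 and stress granule proteins, 12 were positive and 12 negative, and none passed, adjusted over the list alone or over all genes (camera adjusted p = 0.851).

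NF-kB pathway components did not move as a list. Of 22 tested members, 14 were positive and 8 negative, with a median log2 fold change of 0.02 (camera adjusted p = 0.541). None passed, adjusted over the list alone or over all genes. The smallest p values belonged to Irak2 (0.20, adjusted p = 0.640), Tnip1 (-0.10, adjusted p = 0.715), the inhibitor Nfkbia (0.19, adjusted p = 0.739) and the kinase gene Tbk1 (0.08, adjusted p = 0.761). Only 6 inflammatory cytokines and NF-kB target genes reached the expression filter, with a median of 0.05 (camera adjusted p = 0.530) and Csf1 (0.19) and Gadd45b (0.21) leading. Toll-like receptor and damage signal sensing genes, 5 of which were tested, had a median of 0.04 (camera adjusted p = 0.781).

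Glucocorticoid responsive genes stood higher in CFA. All 18 tested members were positive (median log2 fold change 0.28), and 14 rose when adjusted over the list alone, although 0 passed over all genes. Examples are Pdk4, a brake on pyruvate oxidation (3.48 to 4.78 FPKM, log2 fold change 0.37), Map3k6 (0.33) and the transcription factor gene Klf9 (0.23). Camera with the preset correlation gave an adjusted p of 2.75e-18, against an adjusted p = 0.0637 with an estimated correlation. Nuclear genes of oxidative phosphorylation stood lower, with 20 of 22 members negative and a median of -0.10. Pan-neuronal genes (15 of 16 negative, median -0.08) and synaptic vesicle genes (17 of 20 negative, median -0.08) were lower by camera as well (adjusted p = 0.648 and adjusted p = 0.742 with an estimated correlation, and exact permutation p of the list means 0.0628 and 0.351). Both of these lists hold Syn1, Syt1, Syp and Snap25, so they are not separate evidence. Of the oxidative phosphorylation genes, 5 fell when adjusted over the list alone, among them Ndufs6 (-0.20), Uqcrq (-0.22), Atp5e (-0.22) and Cox7c (-0.14), subunits of respiratory complexes (camera adjusted p = 2.11e-07; adjusted p = 0.0637 with an estimated correlation). The median was -0.06 as TPM and -0.05 over the libraries with Xist (2 saline, 5 CFA), a choice made after seeing the data. As TPM the pan-neuronal median was -0.04 and the synaptic vesicle median -0.04. The median over all tested genes also lay higher as TPM, at 0.03 against -0.00427 in the main fit. These smaller medians thus in part follow a shift of all genes, and camera kept its calls of these lists as TPM.

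Antigen presentation and complement genes were also higher. Of 8 tested genes of MHC class I and antigen processing, 4 rose adjusted over the list alone: H2-D1 (0.42), H2-K1 (0.49), H2-Q4 (0.41) and B2m, the shared light chain (0.33). Reads of the H2 genes can be split between near-identical copies. The list had camera adjusted p = 2.50e-06 and adjusted p = 0.177 with an estimated correlation. Of 8 tested complement genes, 4 rose adjusted over the list alone, C1qb among them (0.33; list camera adjusted p = 6.29e-06, adjusted p = 0.177 with an estimated correlation). All 14 interferon response genes were positive (median 0.25), such as Oasl2 (0.43), Gbp3 (0.33), Irf9 (0.23) and Ifitm3 (0.46), with none past the threshold adjusted over the list alone (camera adjusted p = 2.50e-06, adjusted p = 0.6246 with an estimated correlation). All 20 immediate early genes, which respond to neuronal activity, were positive too (median 0.20), led by Npas4 (0.48), Egr1 (0.39), Nr4a1 (0.51) and Junb (0.31), again with none past the threshold adjusted over the list alone (camera adjusted p = 1.20e-06, adjusted p = 0.6246 with an estimated correlation). The call of the immediate early genes was lost over the libraries with Xist (median 0.09, adjusted p = 0.0840, the highest of 28 alternatives, the lowest being 1.39e-08), and without CFA 3 the median was 0.10. With the striatal list mean as a covariate, chosen after seeing the data, the immediate early median was 0.13 and the camera call held. Without saline 3 the interferon response median was 0.40.

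Resting microglia markers moved in both directions. Of 19 tested, 9 were positive and 10 negative (median -0.01, camera adjusted p = 0.811), and adjusted over the list alone 4 rose and 3 fell. Ctss and the Fc receptor subunit gene Fcer1g (0.38) rose, while Cx3cr1 and the transcription factor gene Sall1 (-0.18) fell in that narrower adjustment; over all genes 1 of the 19, Ctss, passed. The mixed test of fry, which asks whether members change in either direction, gave an adjusted p of 8.60e-07. Reactive microglia genes had 5 positive and 5 negative among 10 tested (camera adjusted p = 0.281), with 1 rise adjusted over the list alone, that of Lyz2. For the reactive list the mixed test of fry gave an adjusted p of 0.0186. The mixed test called 6 lists in all, the glucocorticoid, oxidative phosphorylation, complement and MHC class I lists among them. A call by it was therefore not particular to microglia.

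In all, 15 of 44 lists with enough members moved by camera with the preset correlation, 10 up and 5 down. Other splits of the 12 libraries moved a median of 10 lists by that test (below), so its p-values alone are weak support. With an estimated correlation 0 passed, with 4 at an unadjusted p under 0.05, and fry, which tests a list against no change, called 2 one way, the glucocorticoid and oxidative phosphorylation lists. With Xist as a covariate 9 lists moved, and the pan-neuronal, synaptic vesicle, cholinergic, choroid plexus, ependymal, reactive astrocyte and mitochondrially encoded lists did not. Over the libraries with Xist the immediate early, pan-neuronal, synaptic vesicle and reactive astrocyte lists did not pass, nor did the cholinergic and ependymal lists, whose medians turned sign. With the pan-neuronal list mean as a covariate 9 moved, while the pan-neuronal, synaptic vesicle, cholinergic, striatal, ependymal, reactive astrocyte and mitochondrially encoded lists did not. With the striatal list mean as a covariate 16 moved. The striatal list itself did not, nor did the choroid plexus (median -0.22, camera adjusted p = 0.221) and mitochondrially encoded lists (median 0.05, camera adjusted p = 0.247). MHC class II, border macrophages, neutrophils, T and B lymphocytes and sex-linked genes were not tested, with at most 2 members each past the filter.

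**Figure D2:**
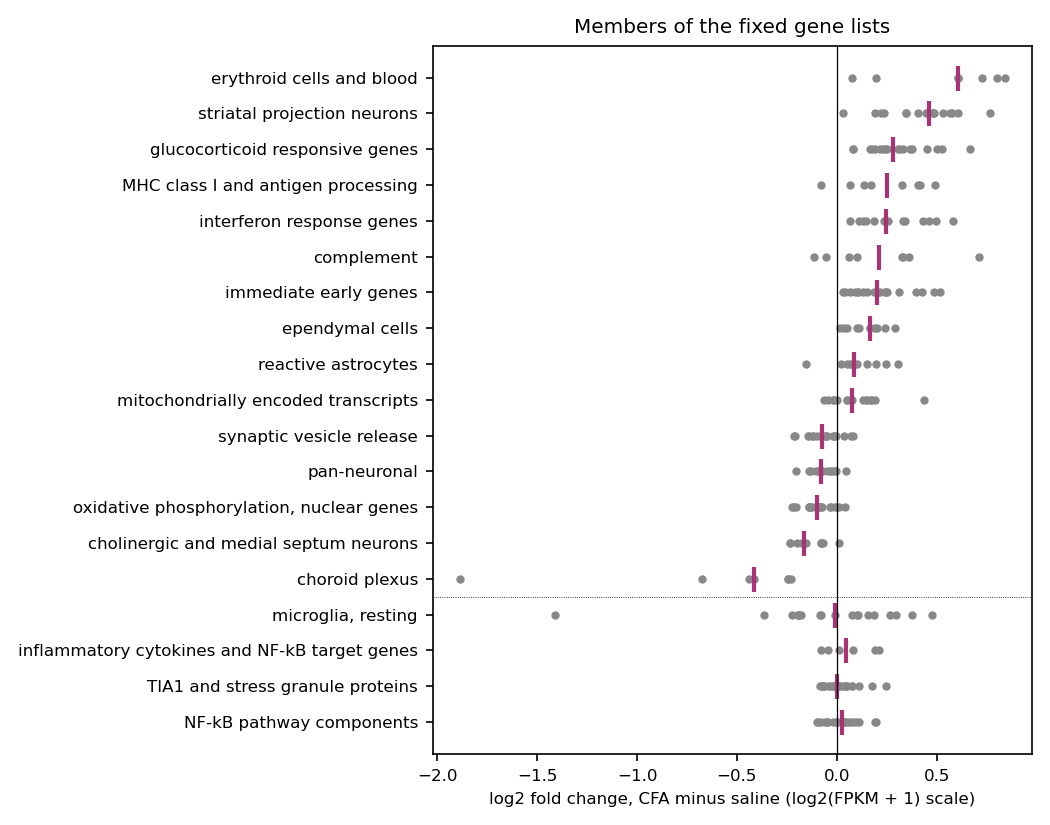
Log2 fold change, CFA minus saline on the log2(FPKM + 1) scale, of every tested member (grey points) of the 15 lists that moved by camera with the preset correlation and, below the dotted line, of 4 lists that did not; red bars are list medians. All 18 glucocorticoid responsive genes lie to the right of 0, and Cx3cr1 is the far left point (-1.41) of the resting microglia row.

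The last comparison asked whether the tissue sampled differed between groups. Markers of striatal projection neurons, neighbours of the septum, had all 16 members positive (median 0.46; Syndig1l 0.45; camera adjusted p = 1.95e-05, adjusted p = 0.742 with an estimated correlation). Erythroid genes had all 7 positive (median 0.60; Alas2 0.84; adjusted p = 0.6246 with an estimated correlation) and ependymal genes all 11 (median 0.16, but -0.0631 over the libraries with Xist, 2 saline and 5 CFA; adjusted p = 0.785 with an estimated correlation). Reactive astrocyte genes (median 0.09, Fkbp5 0.31 and Gfap 0.24, adjusted p = 0.648 with an estimated correlation) and mitochondrially encoded transcripts (median 0.08, adjusted p = 0.684 with an estimated correlation) were higher by camera as well. Fkbp5 is also a member of the glucocorticoid list. Choroid plexus markers had all 7 negative (median -0.41; Ttr -1.89 and Clic6 -0.44; adjusted p = 0.763 with an estimated correlation), but without saline 3 and saline 5 the median was 0.0895 and Ttr 0.29. Pan-neuronal genes (median -0.08; Syn1 -0.14; adjusted p = 0.648 with an estimated correlation), synaptic vesicle genes (median -0.08; Rab3a -0.12; adjusted p = 0.742 with an estimated correlation) and cholinergic and medial septum markers (median -0.16, but 0.11 over the libraries with Xist; adjusted p = 0.742 with an estimated correlation) were lower by camera.

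Several of these camera calls were lost when 1 library was left out. The ependymal list passed in 7 of 12 such fits and was lost without saline 1 (median 0.08), saline 4 (0.13), saline 6 (0.07), CFA 2 (0.07) or CFA 4 (0.08). The choroid plexus list was lost without saline 3 (-0.07), saline 5 (-0.27), CFA 4 (-0.47) or CFA 6 (-0.31), and the cholinergic list without saline 1 (-0.13), saline 4 (-0.12), CFA 2 (-0.11) or CFA 3 (-0.11). The reactive astrocyte list was lost without saline 1 (0.08), saline 4 (0.06), saline 6 (0.08), CFA 2 (0.07), CFA 3 (0.12) or CFA 4 (0.08). The synaptic vesicle list was lost without saline 1 (-0.05), CFA 1 (-0.05) or CFA 2 (-0.06), and the mitochondrially encoded list without saline 4 (0.06) or CFA 1 (0.04). Among calls that held, the striatal median was 0.23 without CFA 1, the erythroid 1.02 without CFA 6, the reactive astrocyte 0.16 without saline 3 and the mitochondrially encoded 0.15 without CFA 4. Quantile normalization ended the calls of pan-neuronal (-0.05), synaptic vesicle (-0.03) and ependymal genes (0.15), and TPM those of ependymal (0.22) and reactive astrocyte genes (0.14). The ependymal call was also lost without a filter (0.11) and with filters at 0.1 (0.11) and 5 FPKM (0.16), and the mitochondrially encoded call without a filter (0.08).

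Compared library by library, 0 of 22 cell type and quality lists differed between groups past the threshold by the exact permutation test. A single list could pass only at the smallest p that test allows, 0.00216. At an unadjusted p under 0.05 there was 1, the nuclear-retained RNA list, which holds Xist. Astrocyte and lateral septum neuron list means differed by -0.01 and -0.05. Striatal markers averaged 3.26 ± 0.365 in saline and 3.68 ± 0.731 in CFA on the log2(FPKM + 1) scale (SD, n = 6 each). Choroid plexus markers averaged 3.37 ± 1.14 and 2.78 ± 0.297. Ttr, the main choroid plexus transcript, was 2259 FPKM in saline 3 and 701 in saline 5 and at most 66.6 in every other library. By genes chosen after their values were seen, Xist was above 1 FPKM in 2 saline and 5 CFA libraries, and Ddx3y, encoded on the Y chromosome, in 4 saline and 1 CFA library, with 0 libraries showing both or neither. The labels give no sex.

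**Figure D3:**
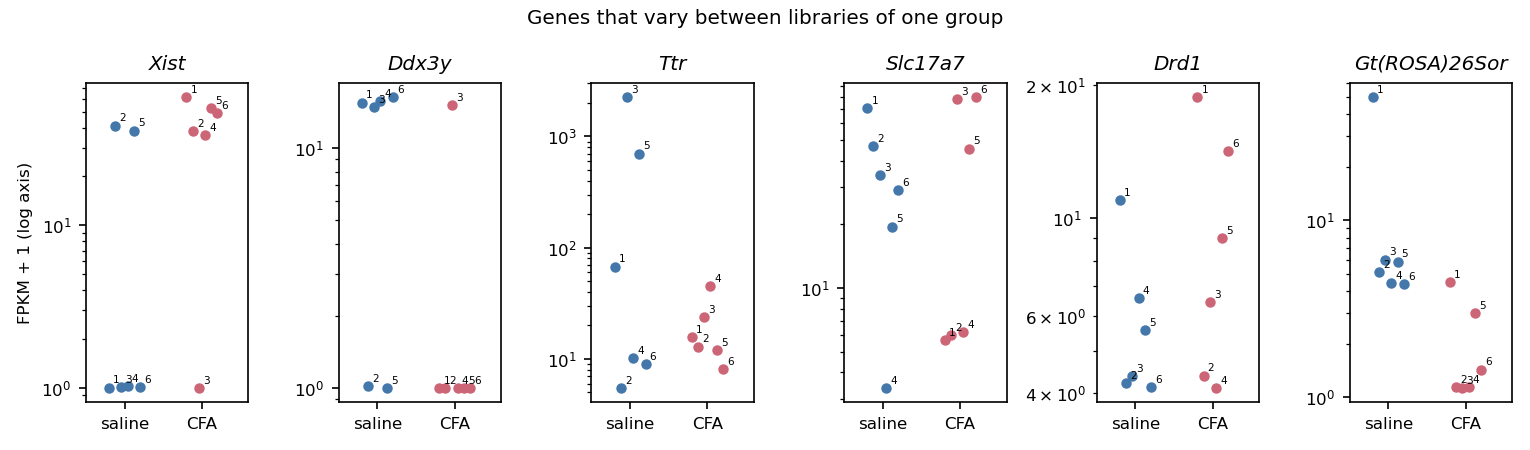
FPKM + 1 on log axes of 6 genes chosen after their values were seen, 1 point per library with its replicate number, saline in blue and CFA in red. Xist and Ddx3y part the libraries into those with and without a Y chromosome, 4 saline libraries and 1 CFA library having Ddx3y, and Ttr reaches 2259 FPKM in saline 3.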

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

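The tests of Cx3cr1 below were chosen after its values were seen; those of the glucocorticoid and oxidative phosphorylation lists were set after the changes of these lists were seen but before the results of the tests, as were the splits of the libraries. The intervals between libraries and the fits over libraries with Xist were added after those results, and the test of neurons was added last, before its own result was seen. Over 160 groups of 6 libraries, for 55 genes, 22 lists and the library measures, 9 had a library standing apart by the gap of that library relative to the group's range, against 8 that chance would give at 1 in 20. Ctss was 19.5 FPKM in saline 6 against 22.8 to 24.6 in the others (gap share 0.664). C1qb was 26.6 FPKM in CFA 3 against 33.1 to 37.7 (0.627). H2afj was 10.7 FPKM in saline 5 against 11.8 to 12.1 (0.815), and Uqcrq 41.1 FPKM in saline 5 against 45.0 to 47.1 (0.667). Atp5e was 42.5 FPKM in saline 3 against 36.6 to 38.6 (0.651). Gt(ROSA)26Sor was 48.98 FPKM in saline 1 against 3.37 to 4.99 (0.870). Astrocyte markers were lowest in saline 1 (mean 5.57 against 5.64 to 5.66; 0.712), GABAergic markers lowest in saline 3 (4.74 against 4.88 to 4.92; 0.762) and striatal markers highest in saline 1 (3.95 against 3.00 to 3.35; 0.639).

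Of the 462 splits of the 12 libraries into 6 and 6, 100 were drawn, the real one included. As many genes as the 4 of the real split were called in 2 of the 100, and the highest of the others called 4. That share lies under 0.05, so chance is an unlikely source of this number of genes but is not excluded. The splits do not tell CFA from other differences between the groups, such as sex. For gene lists, 14 of the 100 splits moved as many as the 15 of the real split, and another reached 20, so chance is not excluded for the number of lists. The other splits moved a median of 10 lists, and none moved fewer than 3. Camera with the preset correlation thus called lists under arbitrary splits too, so its small p-values overstate the evidence for a list.

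Cx3cr1 was lower in 6 of 6 CFA libraries than in any saline library, without passing the threshold over all genes in the main fit. It passed in 5 of 32 alternatives, such as voom on the recovered reads and the fits without CFA 1 or CFA 5. Among CFA libraries it was uneven, at 5.48 FPKM in CFA 1, 6.32 in CFA 5 and 1.68 to 2.14 in the others. Fewer microglia would lower the other resting markers about as far, but their median was 0.0340, against a change of -1.41 for Cx3cr1. Of these 18 markers, 9 were positive and 9 negative. The 95% bootstrap interval of that median, -0.18 to 0.17, was drawn over genes and does not measure the spread between libraries. These values argue against fewer microglia as the whole cause, while a smaller loss is not excluded. The unequal sexes do not account for the lower Cx3cr1 either, since with Xist as a covariate its log2 fold change was -1.57 (95% interval -2.19 to -0.95). Altered or strain-specific alleles in the CFA animals may be a cause: Gt(ROSA)26Sor, a locus used for engineered insertions and chosen after its values were seen, lay below every saline library in 5 of 6 CFA libraries and was also highest in CFA 1 and CFA 5 (3.49 and 1.98 FPKM against 0.13 to 0.43). That cannot be told apart from an effect of CFA for Cx3cr1, because all libraries are labelled wild type and the deposited values hold no sequence reads over these alleles. The same doubt, not tested for them, covers Wdfy1 (6 of 6 CFA libraries below every saline library) and further genes chosen after their values were seen. These are Herc3 (5 of 6 below), Gm11942 (5 of 6 below) and Eif3s6-ps2 (6 of 6 above).

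The glucocorticoid responsive genes had a median of 0.29 with the striatal list mean as a covariate. The 95% interval of the list mean's difference (0.16 to 0.49) stayed above 0.15, 50% of the difference without the covariate. That argues against striatal tissue as the source of over 50% of the difference, while a smaller share stays open. With the choroid plexus list mean as a covariate the median was 0.25, with 17 members positive and 1 negative. Its interval of 0.12 to 0.45 excludes 0 but reaches below that bound, so a share from choroid plexus tissue stays open. With Xist as a covariate the median was 0.28, with an interval of 0.15 to 0.50 that excludes 0 but reaches below that bound, the adjusted p of fry, against no change, went from 0.0144 to 0.0834, and over libraries with Xist the median was 0.20, with an interval of -0.02 to 0.42 that includes 0 (adjusted p of fry 0.486). A share of the difference from sex therefore cannot be told apart from CFA with these sexes per group. The list mean was higher in 6 of 6 CFA libraries than in any saline library, and its exact permutation p of 0.00216, the smallest 924 assignments can give, was 0.0952 after adjustment over 44 lists. An effect of CFA was not tested apart from these, and hormone, handling and time of day, which the labels do not give, stay open.

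The lower oxidative phosphorylation genes have short transcripts (median gene length 1653 bases against 4194 over tested genes). Of 10000 random lists matched on length and expression, 0.040% had a median as low as -0.10. Those lists were drawn gene by gene, while members of the real list can vary together (estimated inter-gene correlation 0.08), so that share can be too small. With that limit, it argues against a general loss of short transcripts as the whole cause. The median of the random lists was -0.03 against -0.00427 over all tested genes, so a part stays open. The median of the oxidative phosphorylation list was -0.11 with the striatal and -0.12 with the choroid plexus list mean as a covariate (95% intervals of the list mean's difference -0.15 to -0.06 and -0.15 to -0.05). With Xist as a covariate the median was -0.0923 and the list mean differed by -0.09 (95% interval -0.14 to -0.04), the adjusted p of fry, against no change, went from 0.0144 to 0.0834, and over the libraries with Xist the median was -0.05, with 7 of 22 members positive and an interval of -0.12 to 0.02 that includes 0 (adjusted p of fry 0.646), so a share from sex cannot be told apart from CFA with 2 saline libraries of that kind. Pan-neuronal (15 of 16 negative, median -0.08) and synaptic vesicle genes (17 of 20, median -0.08), lists that share Syn1, Syt1, Syp and Snap25, were lower too. With the pan-neuronal list mean as a covariate the median of the oxidative phosphorylation list was -0.0889 and its mean differed by -0.08. The interval of -0.13 to -0.03 excludes 0 but reaches past 50% of the difference without the covariate. A share from fewer neurons therefore cannot be told apart from CFA. An effect of CFA was not tested apart from these and stays open.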

How the results depend on the processing

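Alternatives with Xist, striatal, pan-neuronal or list-level choices beyond the plan, and those without both libraries high in Ttr, were chosen after seeing the data. The number of genes changed (4) stayed within 1.5 times under both other pseudocounts, filters at 0.1 and 5 FPKM, 3 scalings, robust variances, protein-coding genes and voom on recovered reads. It was 2 without a filter, 13 with library weights, 7 with the choroid plexus list (the planned composition choice) as a covariate, 13 with the striatal covariate, 1 with the pan-neuronal covariate, 1 with the Xist covariate and 1 over libraries with Xist (2 saline, 5 CFA, so fewer samples). It was 1 with an added 1.5-fold threshold and 1024 at unadjusted p under 0.05. By the rank-sum test it was 0, with a smallest adjusted p of 0.425 (857 genes at unadjusted p under 0.05). With 6 against 6 libraries the smallest p of that test is 0.00216, which 66 genes reached, where 29 would be expected by chance. That floor makes a call among 13345 genes hardly possible, so the 0, for genes of the fixed lists too, tells little. Without both libraries high in Ttr the number of genes was 6, with 1 of the 4 (Wdfy1) among them. With the replicate number as a block it was 1 (Wdfy1). Same-numbered libraries correlated at -0.01 to 0.16, and not every library correlated best with its own number. No clear pairing by number was seen, but so few libraries cannot exclude one. Leaving out single libraries gave 1 to 11: 2 without saline 2, 11 without saline 3, 2 without saline 4, 1 without saline 5, 10 without CFA 1 and 1 without CFA 6. Of 12 such fits Wdfy1 passed in 12, Mpeg1 in 10, Ctss in 5 and Nrip2 in 2. Over all 32 alternatives for each gene, Wdfy1 passed in 31, Mpeg1 in 24, Ctss in 18 and Nrip2 in 10. A similar number of genes therefore did not always mean the same genes. In place of Nrip2, Xlr3b was called with the filter at 0.1 FPKM, B3galt5 as TPM and Cx3cr1 by voom. Genes of the fixed lists past the threshold (1, Ctss) numbered 0 without a filter, under the block, by rank-sum test, with the Xist or pan-neuronal covariate and over libraries with Xist, 3 with library weights, 4 with the composition covariate, 4 without both libraries high in Ttr, 3 with the striatal covariate, 2 by voom, and 0 to 5 leaving out libraries. Lists moved (15) numbered 0 with an estimated correlation, 2 by fry, 0 by exact permutation of list means, 9 with the Xist covariate, 9 with the pan-neuronal covariate, 16 under the block and 11 to 17 leaving out libraries. By exact permutation a single list could not pass over 44 lists. The glucocorticoid list, at the smallest p possible (0.00216), had an adjusted p of 0.0952. Tia1 ranged from 0.00021 to 0.18 leaving out libraries, was -0.0338 with the striatal and -0.0343 with the pan-neuronal covariate (where Tial1 was -0.0446) and 0.28 over libraries with Xist. Marker lists per library stayed at 0 in every alternative run. Over all 12 libraries a single list could pass only at the smallest p the 924 assignments allow, 0.00216. The block and the sets with fewer libraries allow fewer assignments, and in some of them no single list could pass. These counts of 0 are therefore weak evidence of a stable result. Medians turned sign for choroid plexus (0.0131 with the composition covariate, its own list mean; 0.0895 without both libraries high in Ttr, where Ttr was 0.29), for cholinergic (0.11) and ependymal markers (-0.0631) over libraries with Xist, and for striatal markers (-0.00067) with their own mean as covariate; other causes were not tested. Agreement between tables, the other table and joined tables were not run, because 1 table held the 12 libraries. At the depth and spread of these libraries, 13 of 50 simulated genes with a log2 fold of 0.3 were called, a share that can overstate recovery in the real comparison. Depth itself was not varied.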

Other observations

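Lists of receptors, channels and neuropeptides did not move by camera. Glutamate receptors (22 tested, median -0.02, camera adjusted p = 0.781), GABA receptors (16 tested, median -0.05, 0.541), voltage-gated channels (26 tested, median -0.02, 0.281), neuropeptides (22 tested, median 0.06, 0.834) and opioid, cannabinoid and pain-related receptors (18 tested, median -0.04, 0.281) stayed within the change of other genes. Circadian clock genes had 10 positive and 6 negative members (median 0.02, camera adjusted p = 0.579), and hypoxia and glycolysis genes 9 and 6 (median 0.01, 0.387). Cholesterol synthesis (median -0.02, 0.212) and heat shock genes (median -0.09, 0.212) did not move either. Endothelial genes that respond to circulating cytokines had 4 positive and 5 negative members among 9 tested (median -0.04, camera adjusted p = 0.881).

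By genes chosen after their values were seen, some transcripts varied widely between libraries of 1 group. Herc3 was 17.6 to 20.04 FPKM in saline and 2.12 to 19.1 FPKM in CFA, with 5 of 6 CFA libraries below every saline library (log2 fold change -1.61, limma adjusted p = 0.206). Cwc22 was near 2 FPKM in saline 2, 4 and 6 and in CFA 2, 3, 4 and 6, and 12.1 to 31.8 FPKM in the other libraries. Slc17a7, a marker of cortical and hippocampal excitatory neurons, was 2.38 to 69.7 FPKM in saline and 4.70 to 78.7 FPKM in CFA, and the dopamine receptor gene Drd1 was 3.13 to 9.96 FPKM and 3.11 to 17.8 FPKM. Eif3s6-ps2 was 0.58 FPKM in saline and 4.81 in CFA (log2 fold change 1.66, adjusted p = 0.165; 6 of 6 CFA libraries above every saline library), and Gm11942 was 15.9 and 3.27 FPKM (-1.85, adjusted p = 0.126; 5 of 6 below). Both are processed pseudogenes, whose reads can be shared with near-identical copies.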
